A study of Saccharomyces cerevisiae with 68 samples.

How the data were processed

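RNA of 5 Saccharomyces cerevisiae strains was measured on 68 2-colour microarrays. Per the labels' protocols, cells were grown in log phase in rich medium (YPD) at 25C, heat shock was given by adding prewarmed medium so that the mixture reached 37C, RNA was extracted with hot phenol, and labelling was indirect, through amino-allyl nucleotides and cyanine dyes. The deposited table holds the authors' log ratios, taken here as log2, 1 value per open reading frame and array, with missing spots left empty. Neither the labels nor the table state the log base, the normalization within arrays or any centring, and the software for these steps is not given in the sources used here, so scale and centring remain unknown and fold values rest on base 2. Array medians lay between −0.17 and 0.28 in the time courses and between −0.09 and 0.03 at 25C.

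Groups were taken from the labels: 60 arrays of 5 strains at 5, 15, 30, 45, 60 and 120 min in 2 series each, and 8 arrays at 25C of 4 strains against DBY8268. The deposited values of replicates correlated positively across genes in every group, with r between 0.293 and 0.949 in the 30 heat-shock groups and between 0.798 and 0.846 at 25C, although 28 of these groups carried the dyes in opposite channels. The values had therefore already been turned the same way, and no sign was changed. The sign at 25C was taken from LEU2 and URA3, which are deleted in RM11-1a and were low there, and from the ASP3 genes, which are present in S288c and were low in all 4 other strains. K9 had no dye swap in its time courses. Replicates held the same value in 0.431% to 1.68% of genes, so none was a copy of another. The labels do not clearly say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name a different 25C reference for 3 arrays within their series, and 1 array of YPS163 at 60 min is labelled as a technical repeat.

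Of 6297 reading frames 5832 matched a locus tag of the RefSeq annotation of assembly R64, which was used for gene symbols only, and 465 kept their systematic name. Time-course genes needed at least 1 value in each of the 30 groups of strain and time, which left 4360 genes, 974 of them with a value on all 60 arrays. Genes at 25C needed values on at least 6 of 8 arrays and 1 per strain, which left 5306, with 4315 complete. Values were used as deposited. The number of arrays limits the precision: the median moderated SD of an array was 0.294 in the time courses and 0.245 at 25C.

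A linear model was fitted per gene by least squares with the empirical Bayes moderation of limma 3.58.1 (squeezeVar, R 4.3.3, statmod 1.5.0), over all 60 time-course arrays with 30 group means and a dye term, and over the 8 arrays at 25C with 4 strain means and a dye term, since each group had n = 2. Residual degrees of freedom were 29 and 3 for complete genes, and prior degrees of freedom 5.68 and 4.17. The mean of the 5 strains at each time, each strain at 15 min, an F test over the 5 strains at each time, and each strain against the mean of the other 4 at 15 min were tested. The change from 15 to 120 min was fitted on the difference within each of the 10 series. Adjusted p values are Benjamini-Hochberg values of limma per comparison with a threshold of 0.05, and a log2 change of 1 marks 2-fold. The count for M22 against the other 4 strains at 30 min was added after results were seen. Overlap was tested with a two-sided Fisher's exact test with a 95% confidence interval. The dye term passed the threshold in 716 genes, and its median absolute log2 size was 0.062.

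Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed. The rule named 13 heat shock genes and 11 genes for 25C whatever their result, the 6 highest and 6 lowest called genes of the common response at 15 min with the same sign on every measured array, and per strain the 3 highest and 3 lowest called genes whose replicates lay outside the range of all other strains. It further named the 3 smallest p of the F test at 15 min and the 5 smallest of the F test of the change, the 4 highest and 4 lowest at 25C per strain and on their mean with the same sign on the arrays concerned, and up to 4 members with the smallest p of each list. The 24 lists were chaperones and co-chaperones, general stress genes, trehalose and glycogen, antioxidant defence, proteasome, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, glycolysis and fermentation, TCA cycle and respiratory chain, ergosterol synthesis, cell wall, amino acid synthesis, methionine and sulfur, hexose transporters, G1/S cell cycle genes, histones, phosphate starvation genes, iron uptake, seripauperin and cold-shock mannoprotein genes, haploid-specific and mating genes, meiosis and sporulation genes, and strain marker genes. Some share members, such as CTT1 in the general stress and antioxidant lists. Lists were tested with limma's camera on the moderated statistic, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from residuals, adjusted over the lists of a comparison.

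The model was tested on simulated arrays with 200 changed genes. For the common response at 15 min, tested on 4360 genes, it recovered 90% of changes of log2 0.5 and 99.5% of changes of 1. For the F test at 15 min with 1 strain changed, on 4360 genes, it recovered 0% of changes of 0.5, 39% of changes of 1 and 96% of changes of 2. For YPS163 against the other 4, on 4360 genes, it recovered 1.5%, 69% and 99% of changes of 0.5, 1 and 2. For M22 at 25C, on 5306 genes, it recovered 0%, 85% and 98.5%, and for the F test of the change, on 4277 genes, 0%, 0% and 57.5%. When 40% of the variance was shared within a series, false calls of the F test at 15 min on 4360 genes rose to 20%, 16.9% and 12.1% of calls for changes of 0.5, 1 and 2, those of the common response to between 7.98% and 10.7%, and those of YPS163 against the other 4 to between 7.98% and 18.8%. The correlation within a series estimated from the data was 0.34, near the simulated share.

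Alternatives covered centring, scaling of arrays to one spread, the filter on missing values, robust moderation, the dye term, the series and the slide as random blocks, the array code prefix, each time alone, other pairs of times, K9 left out, and each series or array left out in turn. Chosen after seeing the data were scaling within each time, leaving out M22, RM11-1a, the M22 array with the fewest values, the 3 arrays with another 25C reference label and the array labelled as technical, and leaving out near-identical genes at 25C. Where a series left out leaves 1 array in a group, that array is assumed to vary like the others. Leaving out a series or array kept the set of tested genes, a choice made after a first run that filtered genes anew. A change of sign counted as a reversal only where the reported value passed the threshold. Where only the alternative passed it counted as a gained call, and where neither passed as no change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.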

Results

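Heat shock was followed in 5 strains of the budding yeast Saccharomyces cerevisiae on 2-colour microarrays, which hybridise labelled RNA of a test sample and of a reference to the same spots. The laboratory strain DBY8268, which has the S288c background of the reference genome, was studied with 4 strains of other origin: K9, M22, RM11-1a and YPS163. Each strain was moved from 25C to 37C and sampled at 5, 15, 30, 45, 60 and 120 min in 2 series, with the RNA of the same strain at 25C as the reference, which gave 60 arrays. On 8 further arrays each of the other 4 strains was hybridised against DBY8268 at 25C, with 2 arrays per strain. The value table held 6297 open reading frames, and an array gave a value for 3418 to 6098 of them in the time courses (median 5304) and for 4587 to 5659 at 25C (median 5506.5). The number of arrays limited the precision: each strain and time had n = 2. Replicate arrays of a strain and time correlated across genes, which are not independent replicates, with r from 0.649 to 0.901 in K9, 0.842 to 0.949 in M22, 0.593 to 0.919 in DBY8268, 0.441 to 0.839 in YPS163 and 0.293 to 0.792 in RM11-1a.

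The first comparison asked which transcripts changed on average over the 5 strains. Among called genes with the same sign on every measured array, the strongest inductions at 15 min were those of heat shock proteins and stress genes. The membrane protein gene HSP12 (YFL014W) rose by a log2 ratio of 7.79 (SE 0.40, adjusted p = 4.54e-17) and the Hsp70 chaperone gene SSA4 (YER103W) by 7.53 (SE 0.19, adjusted p = 6.43e-28). RTC3 (YHR087W) rose by 6.63 (SE 0.15), the disaggregase gene HSP104 (YLL026W) by 6.35 (SE 0.09, adjusted p = 2.92e-34), the small heat shock protein gene HSP42 (YDR171W) by 6.27 (SE 0.16) and TMA10 (YLR327C) by 5.88 (SE 0.20). The largest declines under the same rule were those of HPT1 (YDR399W, −3.97, SE 0.13, adjusted p = 3e-24) and ADE17 (YMR120C, −3.81, SE 0.33), both of purine metabolism. The malic enzyme gene MAE1 (YKL029C) fell to −3.71 (SE 0.17), the ribosome assembly gene NOP7 (YGR103W) to −3.70 (SE 0.19), the RNA helicase gene DBP2 (YNL112W) to −3.62 (SE 0.12) and RPA135 (YPR010C), a core subunit of RNA polymerase I, to −3.51 (SE 0.08, adjusted p = 6.63e-28). The rule itself required these 12 genes to have the same sign on every array of that time with a value, out of 10. Among other heat shock genes fixed in advance, CTT1 (cytosolic catalase) rose by 5.80 (SE 0.19), the aggregate-sorting gene BTN2 by 5.25 (SE 0.14), polyubiquitin UBI4 by 5.06 (SE 0.43), TPS1 (trehalose synthesis) by 4.00 (SE 0.12), the Hsp90 gene HSP82 by 2.70 (SE 0.11) and SSA1 by 2.06 (SE 0.15), all past the limma threshold. HSP26, TSL1 and SIS1 lacked values in some groups and were not tested. Their values at 15 min had a median of 8.40 on 9 arrays, 5.62 on 7 arrays and 4.10 on 3 arrays of 10.

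Gene groups moved together at 15 min. The counts adjusted over the list alone were the same as those over all genes unless given. All 22 measured chaperone genes rose (median 2.52, camera adjusted p = 6.05e-29), including the mitochondrial HSP78 (5.69, SE 0.13) and the Hsp90 co-chaperone STI1 (3.85, SE 0.10). All 21 measured general stress genes rose (median 4.17, adjusted p = 2.73e-28), with GRE3 at 4.82 and PNC1 at 4.55. Of 9 genes of trehalose and glycogen metabolism 8 rose and 1 fell (median 3.12, adjusted p = 7.99e-08), with TPS2 at 3.54 and GLC3 at 3.12. Of 23 antioxidant genes 19 rose and 4 fell (median 0.88, adjusted p = 2.65e-05), with the peroxiredoxin gene PRX1 at 3.32. All 34 proteasome genes rose (median 1.18, adjusted p = 3.98e-10, adjusted p = 0.122 with an estimated correlation), with RPN7 at 1.56 and the proteasome transcription factor gene RPN4 at 1.59. Of 45 genes of the tricarboxylic acid (TCA) cycle and respiratory chain 38 rose and 1 fell (39 and 1 adjusted over the list alone, median 0.67, adjusted p = 5.67e-05), with citrate synthase CIT1 at 2.53. That call was lost at adjusted p = 0.146 with an estimated correlation.

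Growth-related groups declined at 15 min. All 136 measured cytosolic ribosomal protein genes fell (median −2.53, camera adjusted p = 1.22e-55), with RPS0B at −3.12 (SE 0.08) and RPL12A at −2.97. All 78 ribosome biogenesis genes fell (median −2.17, adjusted p = 3.04e-24, adjusted p = 0.0583 with an estimated correlation), with RRP5 at −3.46 and PWP2 at −2.56. All 18 subunit genes of RNA polymerases I and III fell (median −1.64, adjusted p = 9.99e-08, adjusted p = 0.068 with an estimated correlation), with RPA190 at −3.17. Of 44 amino acid synthesis genes 35 fell and 2 rose (median −0.98, adjusted p = 7.89e-06, adjusted p = 0.15 with an estimated correlation). Of 13 G1/S cell cycle genes 11 fell and 2 rose (median −1.10, adjusted p = 0.00888, adjusted p = 0.122 with an estimated correlation), with ribonucleotide reductase RNR1 at −2.69. All 8 measured histone genes fell (median −1.16, adjusted p = 0.00924, adjusted p = 0.327 with an estimated correlation), with HTA2 at −1.63. Of 10 phosphate starvation genes 9 fell and 1 rose (median −1.25, adjusted p = 0.000835), with the phosphate transporter PHO84 at −2.37. The chaperone, general stress, trehalose, antioxidant, cytosolic ribosomal protein and phosphate lists held with an estimated correlation, the largest adjusted p being 0.022.

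Other lists did not pass the camera threshold as groups at 15 min. Of 54 mitochondrial ribosomal protein genes 24 rose and 12 fell (24 and 11 adjusted over the list alone, camera adjusted p = 0.351). In glycolysis and fermentation 4 of 21 genes rose and 12 fell, with a median of −0.31, a mean of 0.24 and a test direction upward (adjusted p = 0.993). The glucose kinase genes HXK1 and GLK1 rose by 5.55 and 4.62. Ergosterol synthesis had 7 genes up and 11 down of 25 (adjusted p = 0.748), the cell wall list 10 up and 5 down of 19 (adjusted p = 0.337), and iron uptake 1 up and 6 down of 11 (adjusted p = 0.337). Methionine and sulfur genes were split as 9 up and 6 down of 18, with a median of 0.25 against a mean of −0.003 (adjusted p = 0.832). For hexose transporters, 3 of 7 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.26 against a mean of −0.07 (adjusted p = 0.979). Seripauperin and cold-shock mannoprotein genes had 9 up and 3 down of 17 (adjusted p = 0.61), haploid-specific and mating genes 2 up and 1 down of 4 (adjusted p = 0.832), and strain marker genes 2 up and 3 down of 5 (adjusted p = 0.979). Of the meiosis and sporulation list 1 gene was measured, SPS4, which fell to −0.47 (adjusted p = 0.00821).

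Over the course of the shock the mean response was broad and then shrank. With limma, 2935 of 4360 genes changed at 5 min (1358 up, 1577 down), 3404 at 15 min (1663 up, 1741 down), 2936 at 30 min (1768 up, 1168 down), 2356 at 45 min (1468 up, 888 down), 2047 at 60 min (1060 up, 987 down) and 2249 at 120 min (1339 up, 910 down). Changes of at least 2-fold were called in 674 genes at 5 min, 1278 at 15 min, 631 at 30 min, 180 at 45 min, 110 at 60 min and 128 at 120 min. Of the 1278 genes, 1035 had their largest absolute value at 15 min, 180 at 5 min and 58 at 30 min. These genes were picked by their value at 15 min, which favours that time. HSP104 stood at 6.22 at 5 min and 1.77 at 60 min, SSA4 went from 7.53 at 15 min to 2.20 at 45 min, and BTN2 from 6.79 at 5 min to 1.31 at 30 min, while HSP12 remained at 5.01 at 60 min. Centring each array on its median shifted the median of all genes at 30 min by −0.124 and lowered the share of called genes that were higher from 60.2% to 48.3% at 30 min, from 62.3% to 47.2% at 45 min, from 51.8% to 43.1% at 60 min and from 59.5% to 47% at 120 min. The array code prefix as a covariate lowered the count at 120 min to 1425 and at 45 min to 1017. Both RM11-1a arrays at 45 min had a prefix that no other strain had, so part of that fall follows from the design.

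**Figure D1:**
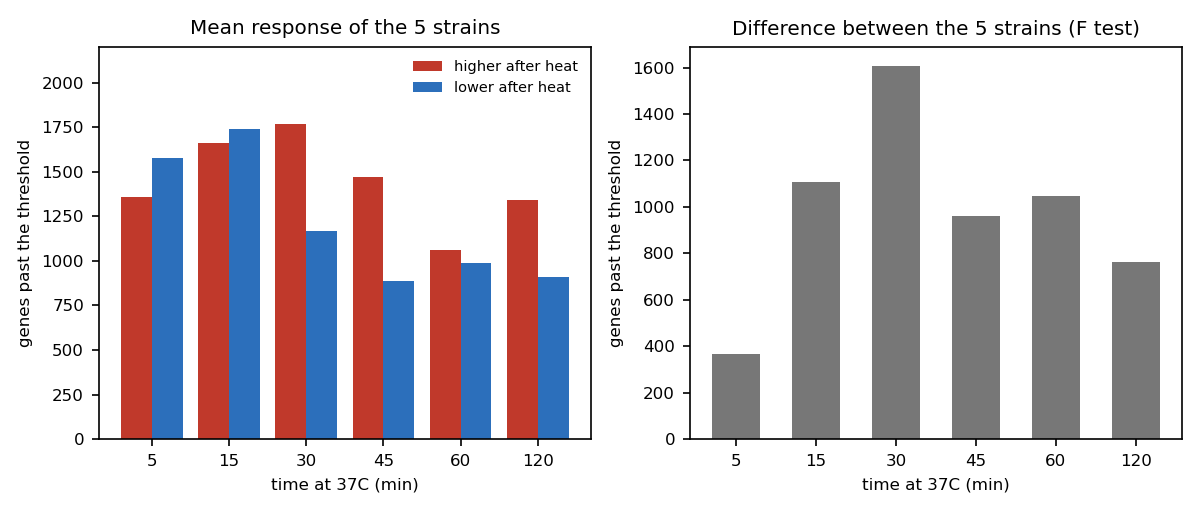
Genes past the limma threshold of 0.05 by time at 37C in minutes, of 4360 tested. Bars on the left count genes higher or lower on average over the 5 strains, and bars on the right count genes that differed between the strains, from 368 at 5 min to 1608 at 30 min.

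At 120 min part of the response persisted. HSP12 was at 3.74 (SE 0.41, adjusted p = 1.44e-08), TMA10 at 2.50, HSP42 at 2.00, HSP104 at 1.92, CTT1 at 1.86, RTC3 at 1.44, TPS1 at 1.34 and SSA4 at 1.11, all past the limma threshold. DBP2 was still lower (−1.51, SE 0.14), as were NOP7 (−0.87) and RPA135 (−0.32). HPT1 (−0.08, adjusted p = 0.643), ADE17 (−0.13, adjusted p = 0.742), MAE1 (−0.21, adjusted p = 0.271) and UBI4 (0.82, adjusted p = 0.107) did not pass. All 21 general stress genes were higher (median 1.66, camera adjusted p = 6.23e-31), as were 14 of 22 chaperone genes, with 1 lower (median 0.55, adjusted p = 1.37e-07). Both calls held with an estimated correlation. Phosphate starvation genes were lower in 7 of 10 and higher in 1 (median −0.33, adjusted p = 0.00115, adjusted p = 0.028 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 127 of 136 and higher in 1 (130 and 1 adjusted over the list alone, median −0.48, adjusted p = 4.72e-22, adjusted p = 0.257 with an estimated correlation). Of the 34 proteasome genes 5 were lower and 1 higher (4 and 1 adjusted over the list alone, adjusted p = 0.0678). Methionine and sulfur genes were higher in 12 of 18 and lower in 1 (median 0.47, adjusted p = 0.00218, adjusted p = 0.187 with an estimated correlation).

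**Figure D2:**
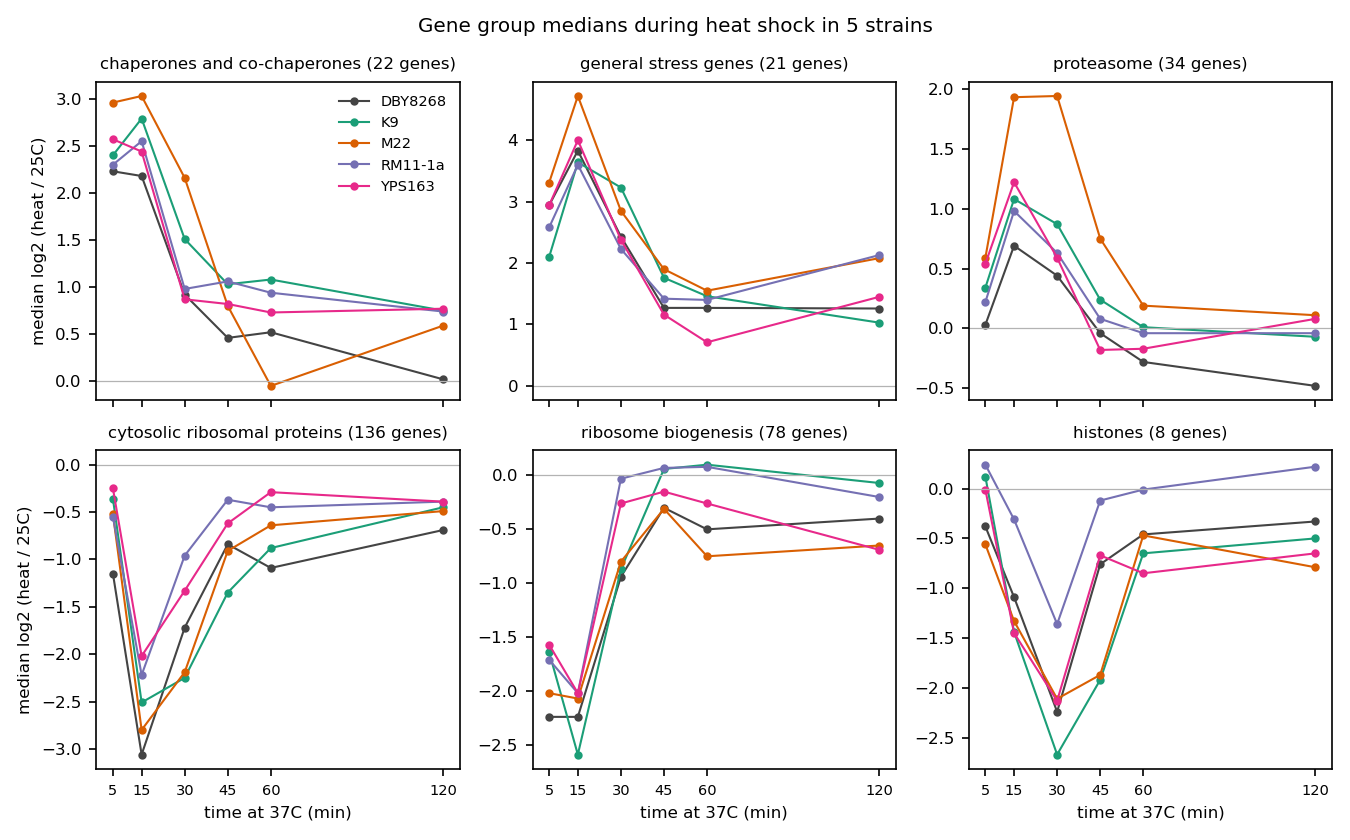
Median log2 ratio of heat over 25C (vertical axes) against minutes at 37C (horizontal axes) for 6 gene groups, with 1 line per strain and each point the median over the measured genes of the fitted strain means (n = 2 arrays per point). Proteasome genes of M22 had medians of 1.93 at 15 min and 1.94 at 30 min, the chaperone median of M22 was −0.05 at 60 min, and histone genes were lowest at 30 min in each strain.

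Each strain's own response was examined at 15 min, the time fixed in advance. All 5 strains induced general stress genes, with medians of 3.83 in DBY8268, 3.64 in K9, 4.72 in M22, 3.60 in RM11-1a and 4.00 in YPS163, and repressed cytosolic ribosomal protein genes, with medians of −3.06, −2.51, −2.80, −2.22 and −2.02 in the same order. The limma fit called 2299 genes in DBY8268 (937 up, 1362 down), 2547 in K9 (1174 up, 1373 down), 2790 in M22 (1349 up, 1441 down), 2336 in RM11-1a (1063 up, 1273 down) and 2403 in YPS163 (1338 up, 1065 down), of 4360 tested. With centred arrays YPS163 had 1161 up and 1229 down, so its excess of induced genes turned. Across genes the mean profiles of any pair of strains correlated with r from 0.876 to 0.917 at 15 min, from 0.705 to 0.836 at 30 min and from 0.264 to 0.604 at 60 min. Scaling all arrays to one spread lowered the counts to 1685 in M22 and 1544 in YPS163, and the array prefix as a covariate lowered them to 1670 in K9 and 575 in RM11-1a. That scaling took all times together and so shrank the wide responses of 15 min. Both RM11-1a arrays at 15 min had a prefix that no other strain had, so the covariate can hardly tell prefix from strain there. Without series 1 of DBY8268 its count was 1392.

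The title of the series asks about interactions of genotype and environment, and the strains were therefore compared in their responses. Each response is a ratio to the strain's own 25C RNA, so a higher or lower response need not be a higher or lower level after heat. The 3 genes with the smallest p of the F test at 15 min were SFA1 (YDL168W, an alcohol and formaldehyde dehydrogenase), ZRT1 (YGL255W, the high-affinity zinc transporter) and OAC1 (YKL120W, the mitochondrial oxaloacetate carrier). SFA1 rose in M22 by 2.66, in RM11-1a by 2.07 and in K9 by 1.81 (SE 0.15), and stood at −0.21 in DBY8268 (adjusted p = 0.235) and 0.16 in YPS163 (adjusted p = 0.369). ZRT1 fell to −5.47 in M22 (SE 0.23) and to −2.92 in RM11-1a, and was at 0.27 in K9 (SE 0.33, adjusted p = 0.505). OAC1 rose in M22 by 2.56 (SE 0.24) and in YPS163 by 1.41 (SE 0.34), fell in K9 to −1.22 and in RM11-1a to −0.92, and was at −0.44 in DBY8268 (adjusted p = 0.122). Strain differences were called in 368 genes at 5 min, 1107 at 15 min, 1608 at 30 min, 961 at 45 min, 1047 at 60 min and 764 at 120 min of 4360. The median SD between strains was 0.315 at 15 min, where noise alone gave 0.199, against an SD of the common response over genes of 1.175. At 60 min the SD between strains was 0.31 and that of the common response 0.42. These counts depended on single libraries and settings: without M22 they were 165, 485, 734, 375, 277 and 315 in order of time, and without the 3 arrays with another 25C reference label 30 min had 873, fewer than the 1060 of 15 min. Without M22 series 1 the counts were 181, 711, 947, 525, 475 and 412 and without its series 2 190, 531, 987, 474, 493 and 478. Without DBY8268 series 1 they were 186 at 5 min and 497 at 120 min, and the count at 5 min was 569 without YPS163 series 1 and 603 without its series 2. With each time fitted alone they were 0, of 619 at an unadjusted limma p under 0.05, at 5 min, 38 at 15 min, 162 at 30 min, 150 at 45 min, 644 at 60 min and 226 at 120 min.

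M22 differed from the mean of the other 4 strains in 624 genes at 15 min (341 higher, 283 lower). OAC1 (difference 2.85, SE 0.27, adjusted p = 3.48e-09), the cell wall glycoprotein gene YGP1 (2.10, SE 0.41) and the nicotinamidase gene PNC1 (1.92, SE 0.25) were higher. The siderophore transporter gene SIT1 (−4.10, SE 0.77, adjusted p = 0.000422), ZRT1 (−4.05, SE 0.27, adjusted p = 2.87e-12) and the pseudogene YIR043C (−3.24, SE 0.25) were lower. Proteasome genes rose more in M22 in 28 of 34 (34 adjusted over the list alone), with a median difference of 0.94 (camera adjusted p = 7.59e-24, adjusted p = 0.0146 with an estimated correlation), among them RPN6 (1.21, SE 0.19) and RPT3 (1.18, SE 0.20). Iron uptake genes were lower in 10 of 11 (median difference −2.12, adjusted p = 8.58e-08, adjusted p = 0.0406 with an estimated correlation), among them the siderophore transporter ARN1 (−2.90, SE 0.64) and the ferric reductase FRE1 (−0.94, SE 0.24). Hexose transporters were lower in 5 of 7 (6 adjusted over the list alone, median −1.30, adjusted p = 8.58e-08, adjusted p = 0.000662 with an estimated correlation), among them HXT2 (−2.48, SE 0.26). Phosphate starvation genes were lower in 5 of 10 (6 adjusted over the list alone, median −0.66, adjusted p = 1.31e-05, adjusted p = 0.000932 with an estimated correlation). At 30 min M22 differed in 979 genes (699 higher, 280 lower), a count of 563 without M22 series 1, 305 without series 2 and 74 with arrays scaled to one spread. At 15 min the count was 312 without M22 series 1, 96 without series 2, 210 with the arrays of each time scaled and 10 with all arrays scaled to one spread, a scaling that ended the calls of YGP1, PNC1 and SIT1. In the last 3 of these settings DBY8268 had more, with 780 and 108 under the scalings, so the order of the strains by count depended on the setting. Scaling to one spread took all times together and shrank the wide responses of 15 min, so part of its low counts follows from the scaling itself.

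**Figure D3:**
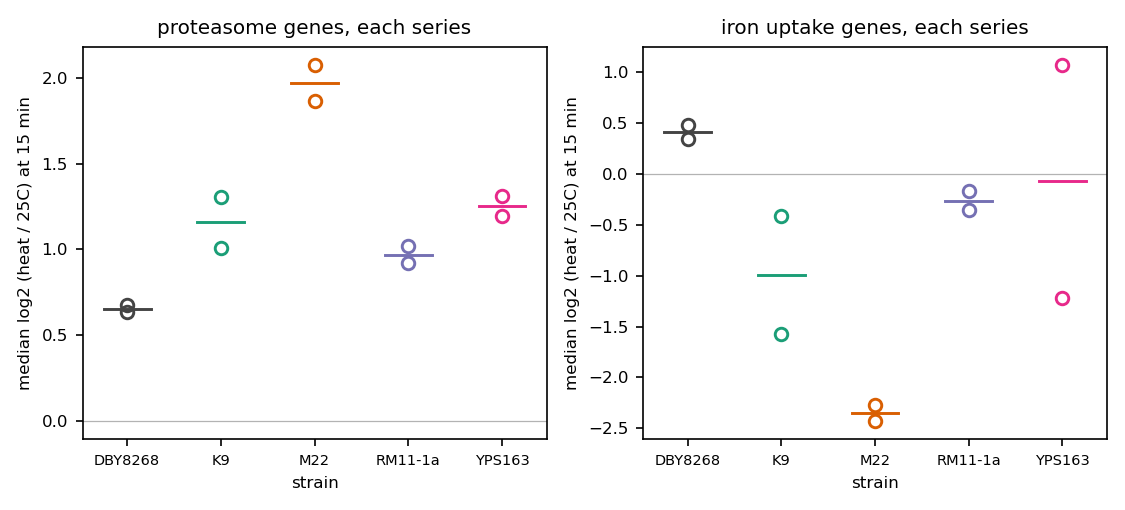
Median log2 ratio of heat over 25C at 15 min (vertical axes) over the proteasome genes and over the iron uptake genes for each of the 10 series, with strains on the horizontal axes, circles for single series and bars for the mean of both. The M22 series have proteasome medians of 1.865 and 2.075 against 0.635 to 1.31 in the 8 others, and iron uptake medians of −2.43 and −2.27 against −1.57 to 1.07.

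DBY8268 differed from the other 4 strains in 450 genes at 15 min (83 higher, 367 lower). ADE17 (3.80, SE 0.77, adjusted p = 0.00141), GCV1 of glycine cleavage (3.15, SE 0.82, adjusted p = 0.0114) and MTD1 of folate metabolism (3.00, SE 0.32, adjusted p = 2.86e-07) were higher, and the cell wall gene SPI1 (−2.44, SE 0.52), YNL134C (−2.32, SE 0.24, adjusted p = 8.36e-08) and PRM10 (−2.14, SE 0.35) were lower. Proteasome genes were lower in 17 of 34 (27 adjusted over the list alone, median −0.69, camera adjusted p = 7e-13, adjusted p = 0.179 with an estimated correlation), with RPN1 at −0.89. Their median response in DBY8268 itself was 0.69, a smaller rise than in the other strains. Cytosolic ribosomal protein genes were lower in 23 of 136 (62 adjusted over the list alone, median −0.61, adjusted p = 1.24e-10, adjusted p = 0.472 with an estimated correlation). The co-chaperone gene FES1 (−1.55, SE 0.18) was also lower. In the other direction, the median response of 11 iron uptake genes was 0.5 in DBY8268, beside −0.75 for the mean of the 5 strains. The count was 76 without DBY8268 series 1, 126 without series 2, 716 without YPS163 series 2, 264 without M22 series 2, 780 with the arrays of each time scaled, 16 with 15 min fitted alone, 108 with arrays scaled to one spread, 103 with the array prefix and 254 without M22. MTD1 and YNL134C kept their calls under all alternatives run, and the other 4 named genes lost theirs under at least 1.

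K9 differed in 165 genes (85 higher, 80 lower). The glucose transporter gene HXT4 (2.85, SE 0.46, adjusted p = 0.000188), malate dehydrogenase MDH2 (2.72, SE 0.29, adjusted p = 8.89e-07) and MBR1 (2.32, SE 0.47) were higher, and MTD1 (−2.53, SE 0.33), the thiamine synthesis gene THI20 (−2.03, SE 0.30) and YGP1 (−2.01, SE 0.42) were lower. Hexose transporters were higher in 5 of 7 and lower in 1 (6 and 1 adjusted over the list alone, median 1.43, camera adjusted p = 1.77e-07, adjusted p = 0.000577 with an estimated correlation), with HXT7 at 1.66 and HXT3 at 1.43. Phosphate starvation genes were higher in 5 of 10 (8 adjusted over the list alone, median 0.69, adjusted p = 3.33e-09, adjusted p = 1.15e-06 with an estimated correlation), with the acid phosphatase gene PHO5 at 1.70 (SE 0.28). Their median response in K9 itself was −0.55, a smaller fall than in the other strains. Seripauperin and cold-shock mannoprotein genes were higher in 6 of 17 and lower in 1 (11 and 2 adjusted over the list alone, median 1.03, adjusted p = 2.1e-10, adjusted p = 0.0115 with an estimated correlation), with PAU2 at 1.84 (SE 0.23). TCA cycle and respiratory genes were higher in 5 of 45 (7 adjusted over the list alone, median 0.37, adjusted p = 7.76e-09, adjusted p = 0.0493 with an estimated correlation), with NDE1 at 1.11. Both K9 series carried the heat-shocked RNA in the same channel, so its dye bias was estimated from the other strains. The count was 72 without K9 series 1, 75 with the array prefix, 7 with arrays scaled to one spread and 328 without YPS163 series 1, and MDH2 alone of the 6 named genes kept its call throughout.

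RM11-1a differed in 157 genes (65 higher, 92 lower). The mitochondrial gene COX2 (2.26, SE 0.43, adjusted p = 0.0013), YLL053C (2.25, SE 0.35, adjusted p = 0.000202) and the endochitinase gene CTS1 (2.05, SE 0.22, adjusted p = 3.13e-07) were higher, and CSS1 (−2.02, SE 0.49), ARO5 (−1.80, SE 0.43) and DOG1 (−1.67, SE 0.24) were lower. Histone genes were higher relative to the other strains in 7 of 8 (median difference 1.05, camera adjusted p = 4.81e-13, adjusted p = 0.00629 with an estimated correlation), with HTA2 at 1.27 (SE 0.22) and HTA1 at 1.41 (SE 0.26). URA3 is deleted in RM11-1a, so its heat ratio there is no response, and the strain marker list is not read as a difference of this strain. Both RM11-1a arrays at 15 min carried an array code prefix that no array of another strain had. A fit with the prefix as a covariate can therefore hardly tell prefix from strain there, and calls lost in it do not show a prefix effect. The count was 100 without RM11-1a series 1, 2 with arrays scaled to one spread and 0 with the array prefix as a covariate, where 260 had an unadjusted limma p under 0.05, and each of the 6 named genes lost its call under that covariate.

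YPS163 differed in 233 genes (208 higher, 25 lower). The methionine synthesis genes MET6 (3.47, SE 0.54, adjusted p = 0.000111) and MET17 (2.61, SE 0.40, adjusted p = 0.000111) and the ferric reductase gene FRE1 (2.19, SE 0.24, adjusted p = 4.43e-07) were higher, and PHO84 (−1.58, SE 0.24), the peroxiredoxin gene TSA2 (−1.17, SE 0.23) and isocitrate dehydrogenase IDH2 (−0.98, SE 0.20) were lower. Methionine and sulfur genes were higher in 10 of 18 (11 adjusted over the list alone, median 1.19, camera adjusted p = 2.65e-13, adjusted p = 0.000138 with an estimated correlation), with the methionine permease MUP1 at 1.86 (SE 0.21) and MET14 at 1.31. TCA cycle and respiratory genes were lower in 11 of 45 (17 adjusted over the list alone, median −0.41, adjusted p = 5.31e-21, adjusted p = 0.00031 with an estimated correlation), with QCR2 at −0.87. Their median response in YPS163 itself was 0.27, a smaller rise than in the other strains. Phosphate starvation genes were lower in 1 of 10 (median −0.21, adjusted p = 0.000645, adjusted p = 0.00766 with an estimated correlation), and the median was 0.01 without K9. Strain marker genes, whose comparison includes RM11-1a without URA3, were lower in 1 of 5 (median −0.26, adjusted p = 0.0125, adjusted p = 0.0252 with an estimated correlation). Centring the arrays, which shifted the median of all genes by −0.114 in the YPS163 response, lowered the share of higher genes from 89.3% to 72.5% of 149. The count was 99 without M22 series 1, 147 without DBY8268 series 2, 47 with the array prefix, 3 with arrays scaled to one spread and 354 without K9, and FRE1 alone of the 6 named genes kept its call throughout.

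The decline of the response was tested on each series' difference of 120 min minus 15 min. Averaged over strains, 2790 of 4277 genes changed, 1613 upward and 1177 downward, of which 643 rose and 290 fell at least 2-fold. The 5 genes with the smallest p of the F test between strains were ZRT1, OAC1, PHO84, MET3 and MRH1. ZRT1 rose in YPS163 by 6.37 (adjusted p = 1.46e-06) and changed by −0.60 in RM11-1a (adjusted p = 0.0842). OAC1 fell in M22 by 2.10 and in YPS163 by 1.18, and rose in K9 by 2.11 and in RM11-1a by 1.06. PHO84 rose by 3.47 in K9, 2.47 in YPS163 and 2.33 in M22, and stood at 0.41 in RM11-1a (adjusted p = 0.211). The sulfate activation gene MET3 rose in M22 by 2.53 (adjusted p = 2.47e-05) and was at −0.53 in YPS163 (adjusted p = 0.0929). MRH1 rose in M22 by 3.04 and fell in YPS163 by 1.34 (adjusted p = 0.00539). The SE of these values was 0.22 to 0.33. Strains differed in this change in 132 genes, of 907 with an unadjusted limma p under 0.05. That count was 17 and 46 without M22 series 1 and 2, 25 and 32 without those of K9, 50 and 45 without those of DBY8268, 15 without strain M22 and 238 for 30 against 120 min, a choice of times that turned the sign of MET3 in M22 and of OAC1 and MRH1 in RM11-1a. MRH1 in YPS163 turned for 15 against 60 min, and ZRT1 in M22 turned with arrays scaled to one spread.

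Basal expression at 25C was compared with DBY8268. On the mean of the 4 strains, the copper transporter gene CTR3 was higher by a log2 ratio of 6.42 (SE 0.12, adjusted p = 4.97e-08), and the iron-related genes FRE4 (3.49, SE 0.31), FRE2 (3.18, SE 0.31) and FIT1 (3.11, SE 0.46) were higher. The asparaginase gene ASP3-2 (−7.02, SE 0.19) and the Ty1 retrotransposon Gag frames YML040W (−6.21, SE 0.10), YPR158C-C (−6.19, SE 0.09) and YHR214C-C (−6.07, SE 0.12) were lower. Near-identical copies can share signal on an array, which leaves the values of the single ASP3 and Ty1 frames uncertain. Of 5306 genes 994 were higher and 1174 lower on the mean of the strains with limma. That total of 2168 was 1311 without K9 array 2 and 1439 without YPS163 array 2, and DBY8268 was one side of each ratio, so the comparisons of the 4 strains share its values.

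In K9, 417 genes were higher and 321 lower. After CTR3 (6.35, SE 0.23) the highest were GTO1 (5.33, SE 0.26) and the vitamin B6 genes SNZ1 (5.04, SE 0.45) and SNO1 (4.71, SE 0.21), and ASP3-2 (−6.29, SE 0.26), the acid phosphatase gene PHO3 (−5.45, SE 0.26), SPL2 (−5.28, SE 0.26) and the mitochondrial intron frame AI4 (−5.22, SE 0.24) were the lowest. Mitochondrial ribosomal protein genes were higher in 43 of 55 (51 adjusted over the list alone, median 0.91, camera adjusted p = 6.71e-21, adjusted p = 0.000769 with an estimated correlation), with MRPL3 at 1.39. TCA cycle and respiratory genes were higher in 27 of 45 (30 adjusted over the list alone, median 0.85, adjusted p = 4.1e-13, adjusted p = 0.0091 with an estimated correlation), with RIP1 at 2.32 and CYC7 at 1.77. The phosphate starvation list was lower in 11 of 14 (12 adjusted over the list alone, median −2.32, adjusted p = 3.56e-14, adjusted p = 0.00418 with an estimated correlation), with PHO89 at −3.75. Chaperones were lower in 8 of 26 (median −0.36, adjusted p = 0.0127, adjusted p = 0.0244 with an estimated correlation), with SIS1 at −0.93. General stress genes were higher in 7 of 24 and lower in 2 (13 and 2 adjusted over the list alone, median 0.57, adjusted p = 0.0415, adjusted p = 0.0333 with an estimated correlation), a call that ended when arrays were centred and when near-identical genes were left out. The total of 738 genes was 186 without array 1 and 150 without array 2 of K9.

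In M22, 541 genes were higher and 688 lower. CTR3 (7.20, SE 0.23, adjusted p = 1.9e-06), the iron-binding mannoprotein genes FIT1 (5.85, SE 0.92) and FIT2 (5.47, SE 1.05) and YJL156W-A (5.37, SE 0.99) were the highest, and the Ty1 frames YHR214C-C (−7.79, SE 0.24), YML040W (−7.73, SE 0.20), YLR256W-A (−7.72, SE 0.28) and YDR098C-A (−7.68, SE 0.29) the lowest. Methionine and sulfur genes were higher in 23 of 25 (24 adjusted over the list alone, median 2.51, camera adjusted p = 7.52e-32, adjusted p = 5.83e-12 with an estimated correlation), with MET2 at 4.50, MET3 at 4.20 and MET14 at 3.95. Chaperones were lower in 13 of 26 (13 lower and 1 higher adjusted over the list alone, median −0.65, adjusted p = 0.00331, adjusted p = 0.0124 with an estimated correlation), with HSP42 at −2.50 and HSP104 at −1.66. Proteasome genes were lower in 14 of 30 (21 adjusted over the list alone, median −0.56, adjusted p = 0.00491, adjusted p = 0.234 with an estimated correlation). Iron uptake genes were higher in 10 of 13 (13 adjusted over the list alone, median 2.36, adjusted p = 0.00037, adjusted p = 0.362 with an estimated correlation), with FRE2 at 5.08. In the phosphate starvation list 13 of 14 genes were lower (median −1.99, adjusted p = 6.48e-05, adjusted p = 0.234 with an estimated correlation). The total of 1229 genes was 437 without array 1 and 449 without array 2 of M22, and 811 with arrays scaled to one spread. FIT1 and FIT2 lost their calls without array 1, and YJL156W-A without either array.

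In RM11-1a, 411 genes were higher and 353 lower. The pheromone receptor gene STE2 (7.18, SE 0.21, adjusted p = 6.02e-06), CTR3 (6.42, SE 0.23), the a-factor gene MFA1 (6.08, SE 0.19) and the agglutinin gene AGA2 (5.50, SE 0.29) were the highest, and the mitochondrial intron frames AI5_ALPHA (−7.28, SE 0.24), AI1 (−6.65, SE 0.35) and AI4 (−6.55, SE 0.24) and ASP3-1 (−6.45, SE 0.16) the lowest. Haploid-specific and mating genes were higher in 10 of 11 (median 3.71, camera adjusted p = 2.06e-43, adjusted p = 1.28e-47 with an estimated correlation), with STE6 at 5.04 and GPA1 at 3.71. RM11-1a is a haploid of mating type a. Strain marker genes were lower in 7 of 9 (median −4.24, adjusted p = 1.47e-27, adjusted p = 1.1e-29 with an estimated correlation), and LEU2 (−5.69, SE 0.27) and URA3 (−6.28, SE 0.31), each with a value on 1 of the 2 arrays, are deleted in this strain. Phosphate starvation genes were lower in 14 of 14 (median −2.13, adjusted p = 1.07e-08, adjusted p = 0.0621 with an estimated correlation), with SPL2 at −3.94. The total of 764 genes was 316 without array 1 and 446 without array 2 of RM11-1a.

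In YPS163, 424 genes were higher and 674 lower, and 529 and 604 with centred arrays. YJL156W-A (6.22, SE 0.99), CTR3 (5.70, SE 0.23), YLL053C (4.60, SE 0.16) and the aquaporin gene AQY2 (4.22, SE 0.30) were the highest, and ASP3-2 (−6.71, SE 0.26) and the Ty1 frames YLR157C-A (−6.63, SE 0.22), YML040W (−6.59, SE 0.20) and YPR137C-A (−6.58, SE 0.23) the lowest. TCA cycle and respiratory genes were higher in 32 of 45 and lower in 1 (35 and 2 adjusted over the list alone, median 1.12, camera adjusted p = 8.01e-16, adjusted p = 0.00303 with an estimated correlation), with cytochrome c gene CYC1 at 3.41 and COX12 at 2.38. Mitochondrial ribosomal protein genes were higher in 42 of 55 (46 adjusted over the list alone, median 0.83, adjusted p = 5.45e-13, adjusted p = 0.0115 with an estimated correlation), with MRPS17 at 1.63. Chaperones were lower in 13 of 26 (15 adjusted over the list alone, median −0.77, adjusted p = 0.00103, adjusted p = 0.00303 with an estimated correlation), with HSP104 at −1.86 and HSP42 at −1.65. The total of 1098 genes was 340 without array 1 and 332 without array 2 of YPS163, and YJL156W-A lost its call without array 1.

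Genes fixed in advance for 25C also differed between strains. On single arrays LEU2 read 0.43 and 1.08 in M22, 0.89 and 0.96 in YPS163 and −0.29 and −0.28 in K9. URA3 read −1.11 and −0.84 in M22, −0.24 and −0.86 in K9 and −0.19 and −0.72 in YPS163. The sodium pump gene ENA1 was lower in M22 (−4.20, SE 0.24), RM11-1a (−2.92, SE 0.16) and YPS163 (−1.02, SE 0.16) and stood at −0.40 in K9 (adjusted p = 0.166), and ENA2 was at −3.54 in M22. ASP3-1 was lower in each of the 4 strains, from −6.85 in M22 to −5.22 in K9. The M22 value is a dye-adjusted fit to 1 array, which read −6.36, so the order of the strains is not read. The metallothionein gene CUP1-1 was lower in K9 (−2.30, SE 0.33), YPS163 (−1.46) and RM11-1a (−1.26) and was at −0.09 in M22 (adjusted p = 0.86). The heme-responsive regulator gene HAP1 was lower in YPS163 (−1.80, SE 0.15), RM11-1a (−1.58) and M22 (−1.04) and was at −0.50 in K9 (adjusted p = 0.0795). AQY2 was higher in K9 (1.74) and M22 (2.04), and AQY1 was at 0.67 in K9 (adjusted p = 0.0351) and 0.58 in YPS163 (adjusted p = 0.0446). For FLO11 and the sulfite pump gene SSU1 no strain passed limma's threshold, SSU1 standing at 1.19 in M22 (adjusted p = 0.0528). Ergosterol synthesis genes were higher in 10 of 25 in K9, 15 in M22, 15 in RM11-1a and 16 in YPS163 (14, 18, 17 and 20 adjusted over the list alone, with 1 lower in K9), with ERG28 at 2.40, 2.64, 2.58 and 2.24. Their camera adjusted p values of 2.64e-06, 1.28e-06, 1.82e-06 and 9.37e-07 became adjusted p = 0.367, 0.315, 0.513 and 0.48 with an estimated correlation. Calls lost on leaving out single arrays were those of AQY1 and CUP1-1, of AQY2 in K9 and M22, of HAP1 in M22 and of ENA1 and ENA2 in YPS163.

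**Figure D4:**
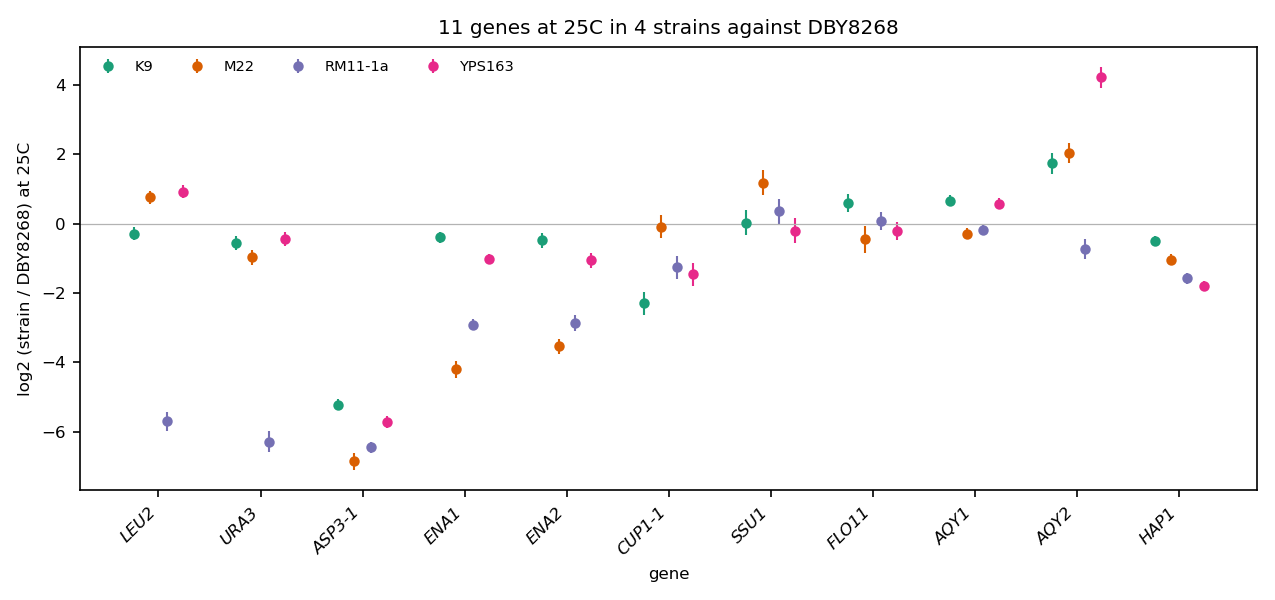
Log2 ratio of each strain over DBY8268 at 25C (vertical axis) for 11 genes chosen in advance (horizontal axis), with points for the fitted mean of 2 arrays, or of 1 where the other had no value, and bars for the limma standard error. LEU2 and URA3 are at −5.69 and −6.28 in RM11-1a, and ASP3-1 lies between −6.85 and −5.22 in the 4 strains.

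The last comparison asked whether genes that differed between strains at 25C also differed in the heat response at 15 min. ZRT1, which fell most in M22 on heating, was higher in M22 at 25C by 2.55 (SE 0.22) and lower in K9, at −2.26 (SE 0.22). CTS1, whose response was higher in RM11-1a, was lower there at 25C, at −4.06 (SE 0.20). OAC1 was higher at 25C in RM11-1a by 2.24 (SE 0.14) and in M22 by 0.99. Of 4056 genes tested in both, 1585 differed at 25C in at least 1 strain and 1035 in the response, and 554 differed in both against 404 for independent lists (odds ratio 2.22, 95% confidence interval 1.92 to 2.57, two-sided Fisher's exact test, p = 9.42e-28). The test takes genes as independent, which they are not, so its p and interval do not measure replication over strains. Genes with little noise can pass more easily in both tests, and the overlap was not adjusted for that. The direction of the overlap held under all alternatives run, with an odds ratio of 1.67 when the arrays of each time were scaled, 4.82 when arrays were scaled to one spread and 27.85 with 15 min fitted alone. The labels do not say whether the 25C arrays used the 25C RNA of the time courses, in which case both lists would share chance values.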

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

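Among the tests of explanations, those of a lower or a higher 25C level in M22, also against the other 4 strains, and the choice to count M22 at 30 min, were made after the results were seen, as were the settings without M22, without single arrays and with each time scaled. Each result here came from a test of a difference between strains in the response to the same heat shock, with limma or camera.

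Strain differences were called in 368 genes at 5 min, 1107 at 15 min, 1608 at 30 min, 961 at 45 min, 1047 at 60 min and 764 at 120 min, and in 132 genes for the change from 15 to 120 min. Against the other 4 strains at 15 min, the counts were 450 in DBY8268, 165 in K9, 624 in M22, 157 in RM11-1a and 233 in YPS163, and 979 in M22 at 30 min. In K9 the median difference was 1.427 for hexose transporters, 0.693 for phosphate starvation genes, 1.027 for seripauperin genes and 0.365 for TCA cycle and respiratory genes. In M22 it was 0.944 for proteasome, −2.119 for iron uptake, −1.302 for hexose transporter and −0.658 for phosphate starvation genes. In RM11-1a it was 1.053 for histones and 0.059 for strain markers, where URA3, 1 of the 2 called genes, is deleted in RM11-1a and its ratio is no response, and in YPS163 1.194 for methionine and sulfur, −0.406 for TCA cycle and respiratory, −0.205 for phosphate starvation and −0.259 for strain marker genes.

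Proteasome genes rose more in M22 at 15 min than in the other strains. A single deviating series is excluded, since both M22 series, at 1.865 and 2.075, lay above the 8 others (0.635 to 1.31). A lower level of these genes in M22 at 25C, at a median of −0.562 over 30 genes, did not fully account for the values measured here. Added to the response difference of 1.285 from DBY8268 it left a median of 0.705 (SD 0.274), above 0 in 30 of 30 genes. The same sum was 0.059 in K9, 0.197 in RM11-1a and 0.29 in YPS163. Against the mean of the other 4 strains M22 kept 0.61 (SD 0.214), also above 0 in 30 of 30. Genes are not independent replicates and each group had n = 2, so these SDs and counts do not measure the error between arrays. A larger spread of the M22 arrays stays open, because scaling within each time left a median of 0.63 with 12 of 34 genes called. A difference of the strain itself may also contribute and was not tested apart from these.

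Iron uptake genes fell more in M22 at 15 min. A single deviating series is excluded, as the M22 medians of −2.43 and −2.27 lay below the 8 others (−1.57 to 1.07). A higher level in M22 at 25C could account for the pattern: the median 25C ratio was 1.84, the response difference from DBY8268 −2.837, and the median of their sum 0.107, or −0.139 against the mean of the other 4 strains. It stays open because 5 of 10 genes had a sum above 0 and the sums had an SD of 1.53, so a median near 0 decides nothing, a stricter bound that was added after the value was seen. A difference of the strain in its response also stays open and was not tested apart from this.

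Most genes with a strain difference were called at 30 min, 1.453 times the count of the next highest time. M22 alone is excluded as the source, since without it the ratio was 1.513, with 734 genes at 30 min and 485 at 15 min. Without the M22 array with the fewest values the ratio was 1.082. With arrays scaled within each time it was 1.042 (1083 against 1039), and both values fell short of the 1.2 set as a bound. The setting without M22 lacked that array too and kept the maximum at 30 min, which argues against that array as the only source. Unequal spread of the arrays stays open. Without the 3 arrays with another 25C reference label, 30 min had 873 genes and 15 min 1060, and with each time fitted alone 60 min had the most, 644. The place of the maximum may rest on a few arrays at 30 min, and a difference of the strains that is largest at that time stays open and was not tested apart from these.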

How the results depend on the processing

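The tests without M22, RM11-1a or the M22 array with the fewest values, without the 3 arrays with another 25C reference label or the array labelled technical, with the arrays of each time scaled, and without near-identical genes at 25C were chosen after results were seen. Over 716 recomputed counts of 30 results, 588 stayed within 1.5 times the reported count. Of 4834 recomputed values of 239 named genes, 4656 kept direction and side of the threshold, 142 lost and 31 gained a call and 5 reversed, and of 5986 values of 257 list results 5587 kept both, 238 lost and 130 gained a call and 31 reversed. List values that passed in neither setting count among those kept. Of the 257 list results, the estimated inter-gene correlation alone took the call from 83 and left 174 the same. For the strains against the rest at 15 min, 58 of 120 list comparisons passed with the preset correlation. Only 14 passed with both the preset and the estimated one. The odds ratio of the overlap kept its direction in all 37. The choice between several probes of a gene was not run, since each gene had 1 value. Signal over background is not in the table used here, so its limit on dim spots could not be set, and missing values stand in its place. Apart from smaller gene or array sets, the cause of the changes was not tested.

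With only complete genes, fewer genes were tested, and the counts were 717, 836, 735, 596, 561 and 570 for the common response in order of time, 656 in DBY8268, 673 in K9, 733 in M22, 670 in RM11-1a and 668 in YPS163 at 15 min, 106, 311, 524, 290, 300 and 191 for strain differences in order of time, 171, 22, 198, 24 and 80 for DBY8268, K9, M22, RM11-1a and YPS163 against the rest, 340 for M22 at 30 min, and 750 and 49 for the change and its strain differences. Without a filter 28 genes differed in the change. The array prefix gave 1425 at 120 min and 1017 at 45 min for the common response, 1670 in K9 and 575 in RM11-1a, 714 for strain differences at 15 min, and 103, 75, 386, 0 and 47 for the strains against the rest in the same order, the 0 of RM11-1a beside 260 at an unadjusted limma p under 0.05. Both RM11-1a arrays at 15 min carried a prefix found on no other strain, so its values under this covariate can hardly tell prefix from strain. Scaling to one spread gave 1685 in M22 and 1544 in YPS163, 187, 58, 538, 1750 and 1343 strain differences at 5, 15, 30, 60 and 120 min, 108, 7, 10, 2 and 3 against the rest, 74 for M22 at 30 min and 811 for M22 at 25C. In the time courses it shrank the wide responses of 15 min and enlarged later ones, so part of these shifts follows from the scaling itself. Scaling within each time gave 780 for DBY8268 and 210 for M22 against the rest, 224 for M22 at 30 min and 58 for the change. Each time alone gave 0, 38, 162, 150, 644 and 226 strain differences, 16, 3, 129, 0 and 5 against the rest and 313 for M22 at 30 min, the counts of 0 beside 619 at 5 min and 502 for RM11-1a at an unadjusted limma p under 0.05. Without M22 strain differences were 165, 485, 734, 375, 277 and 315, DBY8268 had 254 and the change 15. Without K9 YPS163 had 354, and with centred arrays 149. Without the 3 arrays with another 25C reference label, 30 min had 873 and 45 min 588 strain differences and M22 at 30 min 311, and without the array with the fewest values the last was 383. From 30 to 120 min 1513 genes changed and 238 differed between strains. The share of higher genes against the rest went from 41.4% to 52.6% in RM11-1a on centring, and with one spread from 51.5% to 71.4% in K9, from 54.6% to 30% in M22 and from 89.3% to 66.7% in YPS163.

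Leaving out a series or array, where a lone array is assumed to vary like the others, gave 1392 to 2398 genes for DBY8268 at 15 min, against the rest 76 to 716 in DBY8268, 72 to 328 in K9, 96 to 754 in M22, 100 to 199 in RM11-1a and 99 to 349 in YPS163, 305 to 1109 for M22 at 30 min, 181 to 603, 531 to 1262, 947 to 1772, 474 to 1065, 475 to 1226 and 412 to 1040 strain differences in order of time and 17 to 168 for the change. At 25C it gave 150 to 801 in K9, 437 to 1398 in M22, 316 to 769 in RM11-1a, 332 to 1272 in YPS163 and 1311 to 2095 on the mean. The series as a replicate block gave 3384 for the common response and 1002 strain differences at 15 min. At 25C the fit without the dye term, which coincides with the replicate number, gave 651, 1112, 703, 947 and 2001. These changes moved no count by over 1.5 times. At each time the 10 arrays came from 10 different series, so a series block had little room to move these counts. It does not show that the 25C reference shared within a series is harmless. Replicate numbers did not clearly pair the strains. For each strain the difference between its replicates was taken per gene, and these differences were correlated between strains. They correlated at −0.039 to 0.332 at 25C and at −0.259 to 0.196 for the series. At 25C the replicate number is also the dye orientation, so the values there can carry dye effects.

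Reversals among genes were MET3 in M22 (−0.34), MRH1 in RM11-1a (−0.21) and OAC1 in RM11-1a (−1.40) from 30 to 120 min, MRH1 in YPS163 (0.80) from 15 to 60 min and ZRT1 in M22 (−1.77) with one spread. Among lists against the rest, scaling within each time and to one spread turned amino acid synthesis in DBY8268 (−0.025, −0.028), antioxidant (−0.012, −0.001), cytosolic ribosomal protein (0.195, 0.138) and general stress genes (−0.369, −0.24) in M22 and strain markers in RM11-1a (−0.007, −0.011). The prefix turned antioxidant (−0.049), proteasome (0.032) and strain marker genes (−0.447) in RM11-1a. Without M22, amino acid synthesis in DBY8268 (−0.005), chaperones in YPS163 (0.032) and seripauperin (−0.038) and strain marker genes (−0.084) in RM11-1a turned, without K9 phosphate starvation genes in YPS163 (0.01), and with complete genes methionine genes in M22 (0.013) and strain markers at 25C in M22 (0.015, also without near-identical genes) and YPS163 (0.17). Single arrays or series turned amino acid synthesis (−0.513 to 0.076), ribosome biogenesis (−0.21 to 0.557) and strain markers (−0.02 to 0.111) in RM11-1a, chaperones (−0.201 to 0.07) and cytosolic ribosomal proteins (−0.001 to 1.286) in YPS163, ergosterol synthesis in K9 (−0.04 to 0.378), glycolysis in DBY8268 (−0.087 to 0.493), and at 25C ribosome biogenesis (−0.02 to 0.425) and strain markers (−0.975 to 0.206) in M22.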

Other observations

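All tests in this part were chosen after the first results were seen. Histone genes were lower in 8 of 8 at 30 min on the mean of the strains (median −2.19, camera adjusted p = 6.44e-15, adjusted p = 0.00109 with an estimated correlation), further than the −1.16 at 15 min, with HTA2 at −2.64 (SE 0.10) and HHT1 at −2.19. By strain the medians at 30 min were −2.24 in DBY8268, −2.67 in K9, −2.11 in M22, −1.36 in RM11-1a and −2.13 in YPS163. Proteasome genes were higher in M22 than in the other 4 strains in 34 of 34 at 30 min (median difference 1.34, adjusted p = 8.57e-33, adjusted p = 0.00297 with an estimated correlation), with the assembly factor gene UMP1 at 2.43 (SE 0.25). G1/S cell cycle genes of M22 were lower in 7 of 13 and higher in 1 at 30 min (8 and 2 adjusted over the list alone, median −1.09, adjusted p = 0.00416 with an estimated correlation), with RNR1 at −2.15 (SE 0.28), and those of YPS163 were higher in 8 of 13 (10 adjusted over the list alone, median 0.78, adjusted p = 6.9e-08, adjusted p = 0.000868 with an estimated correlation), with RNR1 at 1.63 (SE 0.28). Of the M22 arrays at 30 min, series 2 held values for only 3418 reading frames and carried another 25C reference label.

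Late in the time course the mitochondrial lists differed between M22 and YPS163. At 120 min mitochondrial ribosomal protein genes were higher in M22 than in the other 4 in 33 of 54 (42 adjusted over the list alone, median 0.74, camera adjusted p = 5.65e-25, adjusted p = 0.00257 with an estimated correlation) and lower in YPS163 in 24 of 54 (35 adjusted over the list alone, median −0.56, adjusted p = 0.00484 with an estimated correlation). TCA cycle and respiratory genes were higher in M22 in 29 of 45 (35 adjusted over the list alone, median 0.79, adjusted p = 0.000338 with an estimated correlation) and lower in YPS163 in 17 of 45 (23 adjusted over the list alone, median −0.52, adjusted p = 0.00484 with an estimated correlation). Chaperone genes of M22 were lower than in the other strains at 60 min in 11 of 22 (14 lower and 1 higher adjusted over the list alone, median −0.74, adjusted p = 1.59e-07, adjusted p = 0.0312 with an estimated correlation).

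Across 4056 genes, the 25C ratio over DBY8268 and the difference of the 15 min responses from DBY8268 correlated with r = −0.174 in K9, −0.263 in M22, −0.268 in RM11-1a and −0.124 in YPS163. Genes are not independent replicates, and chance alone gives values below 0 if the 25C arrays and the time courses used the same 25C RNA, which the labels do not say. At 25C, changes of at least 2-fold were higher in 241 and lower in 335 genes in M22 and higher in 155 and lower in 377 in YPS163, where centring brought all called genes from 424 higher and 674 lower to 529 and 604, against 202 and 192 in K9 and 233 and 234 in RM11-1a. Missing or diverged genes were not told apart from lower expression.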
